A study of Caenorhabditis elegans with 2 samples.

How the data were processed

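The data were ChIP-seq peak lists for KLF-2, a Krüppel-like zinc-finger protein of Caenorhabditis elegans, in mid-stage embryos. Per the labels, the worms carried KLF-2 tagged with EGFP and 3xFLAG by a CRISPR insertion directed at klf-2, the embryos were collected by bleaching and had an age of 1.5 hours, chromatin was sonicated, and the tagged protein was recovered with an antibody against GFP. The labels give 1 group of 2 biological replicates and no second condition, so the samples were compared only with each other and the peaks with the genome. The strain label places the tagged allele on chromosome II, whereas the annotation used here has klf-2 on chromosome V. The site of the insertion was therefore left open, and the annotated position of the gene was used.

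Every list is in ce11 coordinates per the labels. The authors deposited, for each replicate and for both replicates together, a ranked list and a thresholded list made by irreproducible discovery rate (IDR) analysis, and the notes deposited with each sample state that the lists derive from the alignments of the replicates and from a further file. That file is read here as the control, because the fold change over control tracks derive from it too, and it was not analysed. The peak caller and the aligner, with their versions, are not given in the sources used here, nor is the treatment of reads that map to more than 1 place, on which peaks at repeated genes such as tRNA genes depend. The authors' signal value of a peak comes from their peak caller and is not normalized between lists. It was therefore used to describe, rank or filter peaks within a list. Replicates were compared by rank, with Pearson's r on the log2 scale given beside it without a test. The deposited score of a peak was checked against the file's own IDR columns and is the global IDR on a capped log2 scale, to within 1 unit. The deposited −log10 q-value column was not used in a test. The position of the summit was taken from the deposited offset. No file used here states read numbers, so the depth is unknown, and intervals cover the counting of peaks or genes only.

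The main list was the conservative thresholded list of both replicates with 1032 peaks, a choice made before the data were examined together with the tests, the alternatives, the gene lists and the motifs. It traces back to both replicates: 98.8% of its peaks carry a first component that is a peak of the ranked list of replicate 1 at the same position and signal value, and 99.4% carry a second component from replicate 2. The other series-level list (1027 peaks) has no such component from either ranked list. The lowest −log10 global IDR in the main list was 2.00, so a stricter reading at a global IDR of 0.01 left the list as it was and tests nothing. Of the 1032 peaks, 56 shared their pair of component peaks with a neighbour, which leaves 1004 distinct pairs.

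Genes, transcripts and sequence came from the WBcel235 genome, whose coordinates are those of ce11, with Ensembl release 115 gene models for 19973 protein-coding genes on the nuclear chromosomes. A promoter window ran from 1000 bp upstream to 500 bp downstream of any annotated protein-coding transcript start, and a gene counted as bound when a summit lay in its window. Shares of peaks in windows or at gene classes were set against 1000 random placements of the peaks on their own chromosomes (two-sided permutation tests, smallest possible p = 0.002). The overlap of the replicates' thresholded lists (at least 1 bp) was set against 1000 placements of the peaks of replicate 1 (one-sided permutation test, smallest possible p = 0.001). Ranks were compared over the main peaks with a summit within 100 bp in both ranked lists, with Spearman's rho and 100000 permutations. The side of the transcript start, the share on chromosome X and the share on chromosome arms were tested with two-sided exact binomial tests, against equal numbers for the side and against the share of 29304 distinct transcript starts for the chromosomes. Chromosomes other than X were tested in the same way, with Benjamini-Hochberg adjustment over the 6, after the result for X was seen. Peaks are not independent replicates, so these p-values describe the lists.

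Motifs were searched on both strands within 50 bp of the summit and, in the same peak, in a pair of 50 bp flanks that start 250 bp from the summit. The centre was searched as its left and right parts so that centre and flanks hold as many positions. Two-sided exact McNemar tests were used for CCRCCC, for 20 fixed motifs and for all 2080 6-mers, with Benjamini-Hochberg adjustment within each family. Each of 32 gene lists was tested with a two-sided Fisher's exact test of bound genes against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists. The lists had 980 entries, of which 14 matched no gene. Intervals of shares are exact 95% binomial intervals, and intervals of odds ratios are exact 95% conditional intervals.

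The genes named in the text follow a fixed rule: genes whose promoter window holds 1 of the 20 peaks with the highest signal value; up to 4 bound members of each list, by signal value; klf-2 and the other KLF/SP genes whatever their values; and the nearest genes of the 5 highest-signal peaks outside every promoter window. Small-RNA genes and any other item named outside this rule were chosen after their values were seen. The comparison with tRNA, snoRNA and other non-coding gene classes (summit within 100 bp of the gene) was also added after the 6-mer results were seen. Small-RNA genes here are tRNA, snoRNA and snRNA genes and the RNase P RNA gene rpr-1.

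Alternatives were the other series-level list, the 516 peaks with the best IDR, the 516 peaks with the highest signal value, the thresholded list of each replicate alone, other windows, distances, flanks, expected shares, gene assignments and backgrounds, and, added after seeing the data, the 773 peaks away from small-RNA genes, 1 peak per pair of component peaks and a centre searched as 1 stretch. The tests were also tried on simulated data, after the real data had been analysed. With 10% of random central windows given CCACCC, the motif test was below 0.05 in 100% of 20 runs and that 6-mer ranked first of 2080 in 100%. With no motif planted, 0.00481% of 6-mers were called. The random sites were not matched to the GC content of the real peaks (49% in centres against 37% in flanks). This rate therefore does not carry over to the 6-mers called in the real peaks. A gene list whose members were bound at a rate of 18%, chosen near the rate seen for ribosomal protein genes, among otherwise random bound genes, was recovered in 94.0% of 50 runs over 19973 genes, and 0.129% of tests of the other lists were called. The bound genes were drawn singly, whereas in the data neighbouring genes can share a peak. The rate of 0.129% therefore does not carry over to lists of neighbouring genes such as histones. With 20% of sites moved into promoter windows, the placement test was below 0.05 in 100% of 20 runs, against 5.0% with none moved. All steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.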

Results

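KLF-2 occupancy was measured by ChIP-seq in mid-stage embryos of a worm strain in which the protein carries an EGFP tag, in 1 group of 2 biological replicates. The conservative list of both replicates held 1032 peaks with a median width of 296 bp. Together they covered 289 kb, or 0.288% of the nuclear genome. Their signal values, given by the authors' peak caller, had a median of 93.9 and a maximum of 873. Taken alone, replicate 1 had 436 thresholded peaks and replicate 2 had 456. The ranked lists behind them held 63024 and 50044 peaks. Read depth is not stated in the files, and there was no second condition to compare.

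The first question was whether the replicates marked the same places. Of the 436 peaks of replicate 1, 306 (70.2%) overlapped a peak of replicate 2, against a mean of 0.239% and a highest value of 1.61% over 1000 random placements (one-sided permutation p = 0.001, the smallest possible). In the other direction, 300 of 456 peaks (65.8%) overlapped. The conservative list took in 89.2% of the peaks of replicate 1 and 89.9% of those of replicate 2. For 954 of the 1032 conservative peaks a summit lay within 100 bp in both ranked lists, and their signal values were correlated across peaks (Spearman's rho 0.624, Pearson's r 0.826 on the log2 scale; two-sided permutation p = 1e-05 for rho, the smallest possible). The conservative peaks were selected for appearing in both replicates, which raises this agreement, and peaks are not independent replicates. The peak with the highest signal value, on chromosome V from 12303473 to 12303783 in an intron of frm-7, had a value of 873 in the conservative list, 444 in replicate 1 and 417 in replicate 2.

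**Figure D1:**
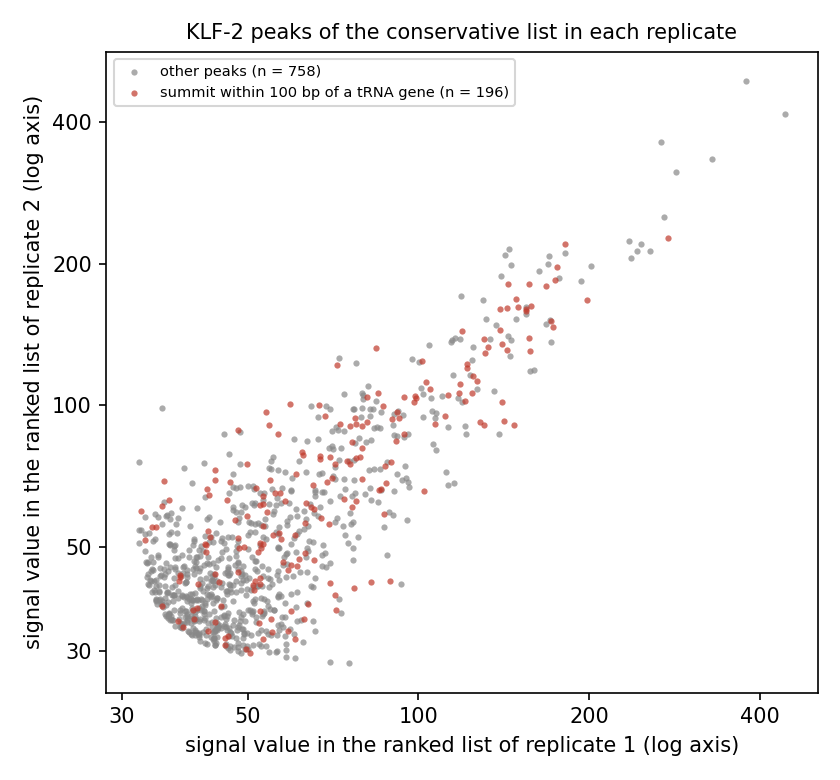
Signal value of each conservative peak in the ranked list of replicate 1 (horizontal, log axis) and of replicate 2 (vertical, log axis), for the 954 peaks matched in both; red points are peaks at tRNA genes. The values rise together (rho 0.624). Red points do not reach the highest values: the highest peak at a tRNA gene, of rank 7, had 276 in replicate 1 and 227 in replicate 2.

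The next question was where the peaks lay relative to genes. KLF-2 summits were enriched in promoters: 482 of 1032 (46.7%) lay in the promoter window of a protein-coding gene, against 31.4% on average for random placements, whose range was 26.9% to 36.1% (two-sided permutation p = 0.002, the smallest possible). Close to transcript starts, they lay more often upstream than downstream. Of the summits within 500 bp of the nearest transcript start, 317 were upstream and 75 downstream (80.9% upstream, 95% interval 76.6 to 84.6%; two-sided exact binomial p = 1.68e-36), and the upstream ones had a median distance of 194 bp. By feature of protein-coding genes, 58.0% of summits were intergenic, that is outside all such genes, against 36.4% of 200 random placements on average. Summits inside tRNA and other non-coding RNA genes count as intergenic here unless they lie in a protein-coding gene. Coding exons held 7.56% against 24.8%, and introns 31.3% against 33.8%, inside the random range of 30.4 to 37.2%.

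A large share of the peaks, and most of the strongest, lay at genes for small structural RNAs. A summit lay within 100 bp of a tRNA gene in 198 peaks (19.2%), against 0.162% on average and at most 0.581% in 1000 random placements (two-sided permutation p = 0.002, adjusted p = 0.00333 over 10 gene classes). In all, 204 of 612 annotated nuclear tRNA genes (33.3%) had a peak. All 204 were among the 587 that share a 36-base stretch with another place in the genome, and 0 of the 25 others had one. The summits fell early in the gene: 159 of the 198 were inside it, at a median of 19 bp from the 5′ end of a gene 72 bp long at the median. Genes for snoRNAs, which guide chemical modification of other RNAs, had 53 peaks (5.14% against 0.126% at random; permutation p = 0.002, adjusted p = 0.00333), and 54 of 346 such genes were marked. At snoRNA genes the summit lay mostly before the gene, with 42 summits upstream, 10 inside and 1 downstream, and a median distance of 41 bp from the 5′ end. Genes annotated as snRNA, which includes spliceosomal and spliced-leader RNAs, had 7 peaks (0.678% against 0.0386%; permutation p = 0.002, adjusted p = 0.00333). Genes for piRNAs had fewer peaks than random placements, with 1 (0.0969% against 1.85%; permutation p = 0.002, adjusted p = 0.00333), as did pseudogenes with 19 (1.84% against 3.38%; permutation p = 0.008, adjusted p = 0.010) and protein-coding genes, counted like the other classes within 100 bp of the gene (48.9% against 66.6%; permutation p = 0.002, adjusted p = 0.00333). Genes annotated only as ncRNA had 215 peaks (20.8% against 2.29%; permutation p = 0.002, adjusted p = 0.00333), 141 of which were also at small-RNA genes. For lincRNA genes (3 peaks) and rRNA genes (0 peaks) no difference was detected. In total, 259 peaks (25%) lay at small-RNA genes. Without them the promoter share of the remaining 773 peaks was 52.4%, and 74 of these 773 (9.57%) still lay at genes annotated only as ncRNA. The comparison with these gene classes was chosen after the sequence results were seen.

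**Figure D2:**
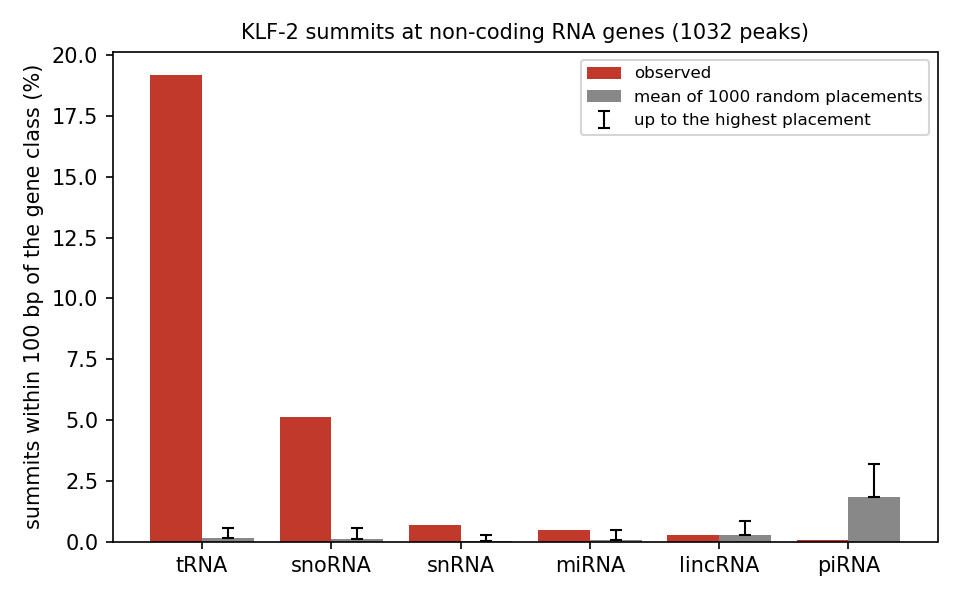
Share of the 1032 summits within 100 bp of each class of non-coding RNA gene (red) beside the mean of 1000 random placements (grey, with a line up to the highest placement). tRNA genes take 19.2% and snoRNA genes 5.14% of the summits, against 0.162% and 0.126% at random.

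The share at tRNA genes followed the height of the peak. Among the 258 peaks with the highest signal values, 100 (38.8%) were at tRNA genes and 12.8% at snoRNA genes. Among the 258 with the lowest values, 12 (4.65%) were at tRNA genes and 1.16% at snoRNA genes. Of the 20 highest peaks, 13 were at small-RNA genes and 9 lay in a promoter window. The 5 highest outside every promoter window were all at small-RNA genes. They were the peak in an intron of frm-7, at the snoRNA genes C51F7.3 and C51F7.4 (nearest transcript start F55C5.17); an intergenic peak on chromosome II from 11960690 to 11960956 at W03C9.9 (nearest W03C9.1); a peak on V from 8500446 to 8500702 in an intron of pxn-1 at ZK994.7; a peak on V from 11314088 to 11314338 in an intron of cutl-18 at T03F7.8; and an intergenic peak on X from 13665460 to 13665699 at a tRNA gene (nearest C04A11.5). The RNase P RNA gene rpr-1, in an intron of ints-8 on chromosome I, had the peak of rank 15 (13463853 to 13464069).

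**Figure D3:**
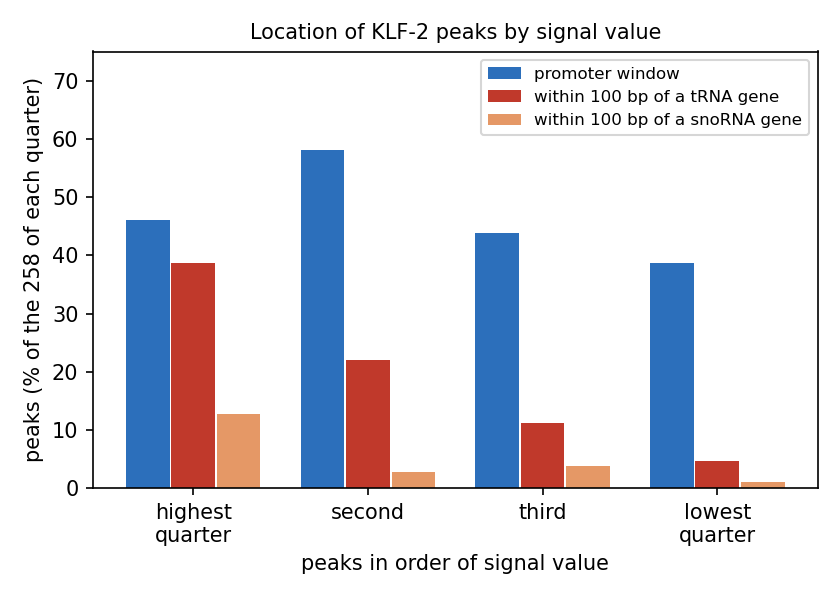
Share of peaks in promoter windows (blue), at tRNA genes (red) and at snoRNA genes (orange) among 4 equal groups of 258 peaks ordered by signal value. The tRNA share runs from 38.8% in the highest group to 4.65% in the lowest.

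The protein-coding genes next to the 20 highest peaks were K12H4.5 (peak on III from 8043836 to 8044093, 530 bp upstream), sre-23, ears-2 and uncp-18, M01F1.9, atx-2 and ecps-1, eel-1, T13C5.6, T02E1.2 and col-85. The peak between ears-2, a glutamyl-tRNA synthetase gene, and uncp-18 lay on chromosome IV from 390382 to 390591, 17 bp and 75 bp upstream of their starts, with signal values of 256 in replicate 1 and 213 in replicate 2. The peak 64 bp upstream of atx-2, the worm ataxin-2 gene, lay on III from 10461216 to 10461427 and had 243 in replicate 1 and 213 in replicate 2. That of T13C5.6 lay 185 bp upstream of its start on X, from 6207795 to 6207978. At sre-23, T02E1.2 and col-85 the peak was also within 100 bp of a snoRNA or tRNA gene.

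Peaks were not spread over the chromosomes as genes are. Chromosome X held 181 peaks (17.5%, 95% interval 15.3 to 20%), above its 14% of transcript starts (two-sided exact binomial p = 0.00168). The excess went with the small-RNA genes: X carries 45.1% of annotated tRNA genes, and without peaks at small-RNA genes its share was 12.2% (exact binomial p = 0.147). Against X's 17.7% of nuclear bases the share of all peaks did not differ detectably (exact binomial p = 0.935). The autosomes, compared after the result for X was seen, departed as well. Chromosome V held fewer peaks than its share of transcript starts (16% against 23.5%, exact binomial p = 3.08e-09, adjusted p = 1.85e-08 over 6 chromosomes), and III (17.8% against 13.4%, adjusted p = 0.000203) and I (18.7% against 14.8%, adjusted p = 0.00124) held more. Without peaks at small-RNA genes the shares were 17.1% on V, 19.5% on III and 19.8% on I (adjusted exact binomial p from 1.42e-05 to 0.000345). Chromosome IV had 14.5% against 17.5% (exact binomial, adjusted p = 0.0148), a call lost without those peaks (15.3%), and II did not differ detectably. On the autosomes, 593 of 851 peaks (69.7%) lay in the arms, defined as the outer parts when each chromosome is cut into 3 equal lengths, against 61.0% of transcript starts (two-sided exact binomial p = 1.53e-07). That call was lost in each replicate alone, where the share was 62.9% in replicate 2 and 63.6% in replicate 1, and against the share of bases (66.7%; exact binomial p = 0.0637).

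The sequence under the summits was compared with the flanks of the same peaks to ask whether the binding site of KLF proteins was more frequent there. CCRCCC, the box that Krüppel-like zinc fingers recognise, was found within 50 bp of the summit in 125 of 1032 peaks (12.1%) and in the flanks of 38 (3.68%; two-sided exact McNemar p = 1.59e-13, adjusted p = 2.80e-12 over 20 motifs). Centres shuffled with their dinucleotides kept held it in 10.1% of peaks on average and in 7.75 to 12.6% over 200 shuffles, and 5 of these reached the observed share (one-sided permutation p = 0.0299). The box has 2 forms: CCGCCC was in 90 centres against 21 flanks and CCACCC in 42 against 17. The CACCC box was in 138 centres against 60 flanks (exact McNemar, adjusted p = 9.67e-09) and the GC box GGGCGG, which is CCGCCC read on the other strand, in 90 against 21 (adjusted p = 1.03e-11). In all, 5 motifs were more frequent at the summit, these 3 overlapping ones among them, and 7 less frequent. The other 2 that were higher were GAGAGA (10.1% against 6.4% of peaks, exact McNemar, adjusted p = 0.00515) and the nuclear receptor sequence AGGTCA (34 against 18, adjusted p = 0.0488), whose call was lost in 5 of 7 alternatives (adjusted p from 0.0103 to 0.631 over them). The lower ones were all rich in A and T: runs of T (30 against 111), the initiator and splice-leader sequence TTTCAG (79 against 184), the SKN-1 sequence RTCAT (179 against 292), the GATA site TGATAA (36 against 94), TATAAA (53 against 100), the homeobox sequence TAATTA (14 against 43) and the PHA-4 sequence TRTTKRY (183 against 232), with adjusted exact McNemar p from 2.80e-12 to 0.0153. The PHA-4 call was lost in 3 of 7 alternatives. The remaining 8 motifs, among them the E-boxes, AP-1, DAF-16, NFY, E2F and heat shock sequences, did not pass.

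**Figure D4:**
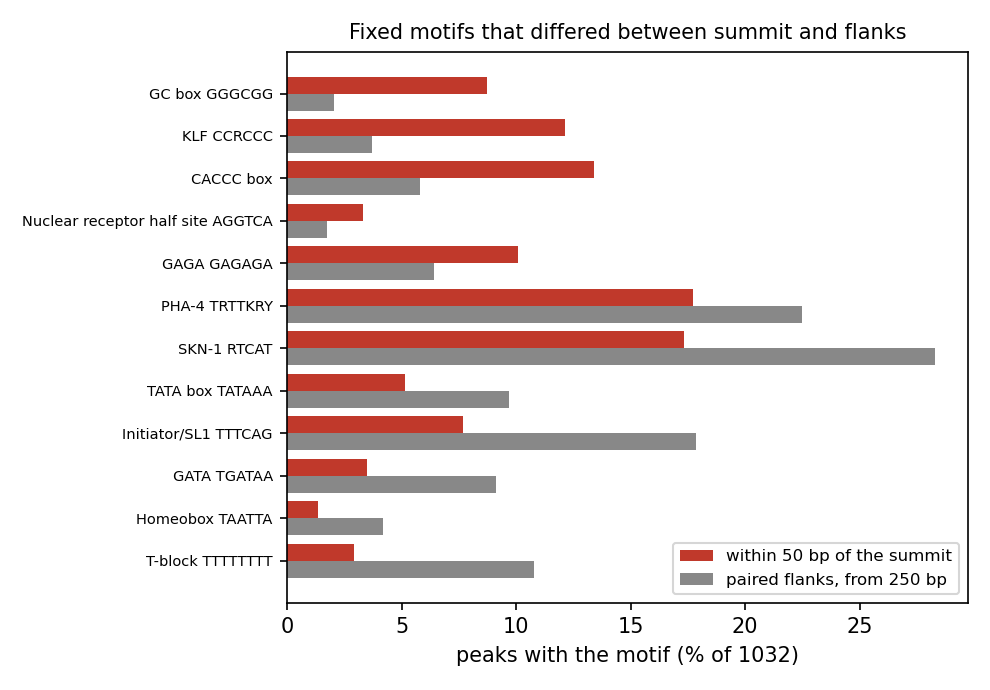
Share of the 1032 peaks with each of the 12 fixed motifs whose frequency differed between summit and flanks, within 50 bp of the summit (red) and in the paired flanks (grey). CCRCCC is in 12.1% of centres and 3.68% of flanks, and the T run in 2.91% and 10.8%.

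Base composition differed between summit and flanks as well. The central 100 bp had 49% G and C, the flanks 37% and the genome 35.4%. At tRNA peaks the centre had 51.8%, and away from small-RNA genes 47.8%. Over all 2080 6-mers, 790 differed at an adjusted p under 0.05, of which 455 were higher and 335 lower at the summit. Those with the smallest p among the higher ones were CGCGCA (96 peaks against 13, exact McNemar, adjusted p = 9.83e-16), CGAACC, whose complement is GGTTCG (127 against 30, adjusted p = 3.68e-15), and ACCACT (127 against 28, adjusted p = 6.23e-15). GGTTCG is part of the internal promoter of tRNA genes. Without peaks at small-RNA genes 465 6-mers passed, 251 of them higher, led by CGCGCA (85 against 10), GCGCGC (68 against 5) and CGCCGC (80 against 13). CCRCCC was then in 91 centres against 29 flanks (11.8% against 3.75% of 773 peaks; exact McNemar p = 6.68e-10).

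Which gene groups carried promoter peaks was asked of 32 lists. A peak lay in the promoter window of 610 of 19973 protein-coding genes (3.05%). Genes of the protein-synthesis machinery stood out. Of 82 cytosolic ribosomal protein genes, 16 were bound (19.5%, odds ratio 7.88, 95% interval 4.23 to 13.9, Fisher's exact p = 3.04e-09, adjusted p = 9.72e-08). The 16 genes had 16 distinct peaks, none of them at a small-RNA gene. The highest were at rpl-3, 269 bp upstream with a signal value of 225, rpl-15, rps-24 and rpl-43. Genes of other lists shared some of these peaks. That of rpl-12 also counted the chromatin regulator gene lin-54 as bound, and that of rpl-5 the collagen gene col-38. Of 43 translation factor genes, 8 were bound (odds ratio 7.34, 2.93 to 16, Fisher's exact, adjusted p = 0.000652), among them eif-3.C, eif-3.I and eif-3.B, subunits of the initiation factor eIF3, and the elongation factor gene eef-1A.1, whose peak lay near the microRNA gene mir-5549.

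Genes of chromatin and RNA processing followed. Histone genes were bound in 10 of 72 cases (odds ratio 5.19, 2.36 to 10.3, Fisher's exact, adjusted p = 0.000682), through 6 distinct peaks, since paired genes such as his-61 and his-62 or his-67 and his-68 share 1 peak. The test counts these 10 genes as separate, so its p-value and interval do not allow for the shared peaks and overstate the evidence. Chromatin regulators were bound in 8 of 63 cases (odds ratio 4.67, 1.91 to 9.91, Fisher's exact, adjusted p = 0.00510), including set-25, a histone methyltransferase gene, lin-35, the worm retinoblastoma gene, cbp-1, an acetyltransferase gene, and let-418, a Mi-2 gene. Splicing and RNA processing genes were bound in 8 of 71 cases (odds ratio 4.07, 1.68 to 8.57, Fisher's exact, adjusted p = 0.00906), with cfim-2, prp-19, snr-1 and mog-4 the highest. The best peak of cfim-2 lay at a snoRNA gene and that of hrpl-1, a further member, at a tRNA gene, and without peaks at small-RNA genes the list no longer passed (odds ratio 3.43). Of the 10 alternatives, the ribosomal protein list passed in 10 (odds ratios 5.35 to 10.4), translation factors in 8, histones and splicing in 6 each and chromatin regulators in 4. With replicate 1 left out, translation factors and chromatin regulators no longer passed (odds ratios 3.17 and 3.26), and with replicate 2 left out histones (4.57), translation factors (5.81) and chromatin regulators (2.53) did not.

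Several metabolic and cell-maintenance lists had odds ratios above 1 without passing the adjustment. The 5 bound genes of glycolysis and the TCA cycle among 48 were led by idhg-1, an isocitrate dehydrogenase subunit gene with a peak 46 bp upstream, hxk-2, ogdh-1 and dlst-1 (odds ratio 3.71, Fisher's exact p = 0.0152, adjusted p = 0.0694). The cytoskeleton and junction list had 6 of 65, with tba-7, ajm-1, wve-1 and hmr-1 (odds ratio 3.25, Fisher's exact, adjusted p = 0.0694). Endoplasmic reticulum stress had 3 of 20, the disulphide isomerase genes pdi-2 and pdi-6 and the chaperone gene enpl-1 (odds ratio 5.62, Fisher's exact, adjusted p = 0.0878). Heat shock and chaperones had 5 of 61, with dnj-28, hsp-60, dnj-29 and hsp-1, autophagy and lysosome 5 of 63, with cpr-9, atg-18, hlh-30 and epg-2, and cell cycle and DNA replication 5 of 62, with mcm-3AP, lin-35, mcm-10 and hcp-6 (odds ratios 2.75 to 2.85, Fisher's exact, adjusted p = 0.125 for each of the 3). The respiratory chain had 4 of 51, namely cox-6A, nduf-7, cox-5B and cox-6B (odds ratio 2.71, Fisher's exact, adjusted p = 0.186). EGF and Ras signalling had 2 of 24, egl-17 and cnk-1 (odds ratio 2.89, Fisher's exact, adjusted p = 0.379). The peaks of ajm-1, cpr-9 and egl-17 lay at tRNA genes and that of cox-6A at an snRNA gene. These lists were unstable: over the 10 alternatives heat shock had odds ratios of 2.08 to 7.18 and passed in 2, endoplasmic reticulum stress 2.91 to 8.58 and 2, the cytoskeleton list 0 to 6.50 and 2, and glycolysis and the TCA cycle 1.63 to 4.69 and 1. The respiratory chain and the cell cycle list passed in 1 each. Heat shock passed with replicate 1 left out (odds ratio 7.18) and the cytoskeleton list with replicate 2 left out (6.50).

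Lists of tissue and developmental genes were not detectably different from other genes. None of 52 embryonic lineage regulators had one, which allows a bound share of up to 6.85%, nor did 35 intestine genes (up to 10%), 21 glia genes (up to 16%), 33 proteasome genes (up to 10.6%) or 21 vacuolar ATPase genes (up to 16%). Homeobox genes had 1 of 99 (zfh-2), nuclear hormone receptors 5 of 274 (nhr-255, nhr-141, nhr-41 and nhr-193 the highest), body wall muscle 1 of 49 (unc-112), the pharynx list 1 of 30 (peb-1), neurons 3 of 87 (unc-70, daf-19 and dop-1), hypodermis and seam 2 of 44 (ajm-1 and hmr-1), collagens 5 of 176 (col-85, col-185, col-71 and col-98 the highest) and Wnt, Notch, TGF-beta and Hedgehog-related signalling 3 of 131 (mom-1, grl-26 and lin-17). Lipid metabolism, a process in which worm KLF genes have been studied, had 1 of 125 (ech-5; odds ratio 0.255, 0.00639 to 1.45, Fisher's exact, adjusted p = 0.406). Redox and detoxification had 2 of 206 (gst-27 and ugt-24; odds ratio 0.309, 0.0371 to 1.14, Fisher's exact, adjusted p = 0.244). Insulin and TOR signalling had 1 of 59 (ins-39), germline and maternal RNA regulators 2 of 63 (mex-1 and spn-4) and apoptosis and engulfment 1 of 26 (wah-1). The peaks of col-185, nhr-255, nhr-41, mom-1 and grl-26 lay at tRNA genes and that of gst-27 at a snoRNA gene. None of these lists passed the adjustment.

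**Figure D5:**
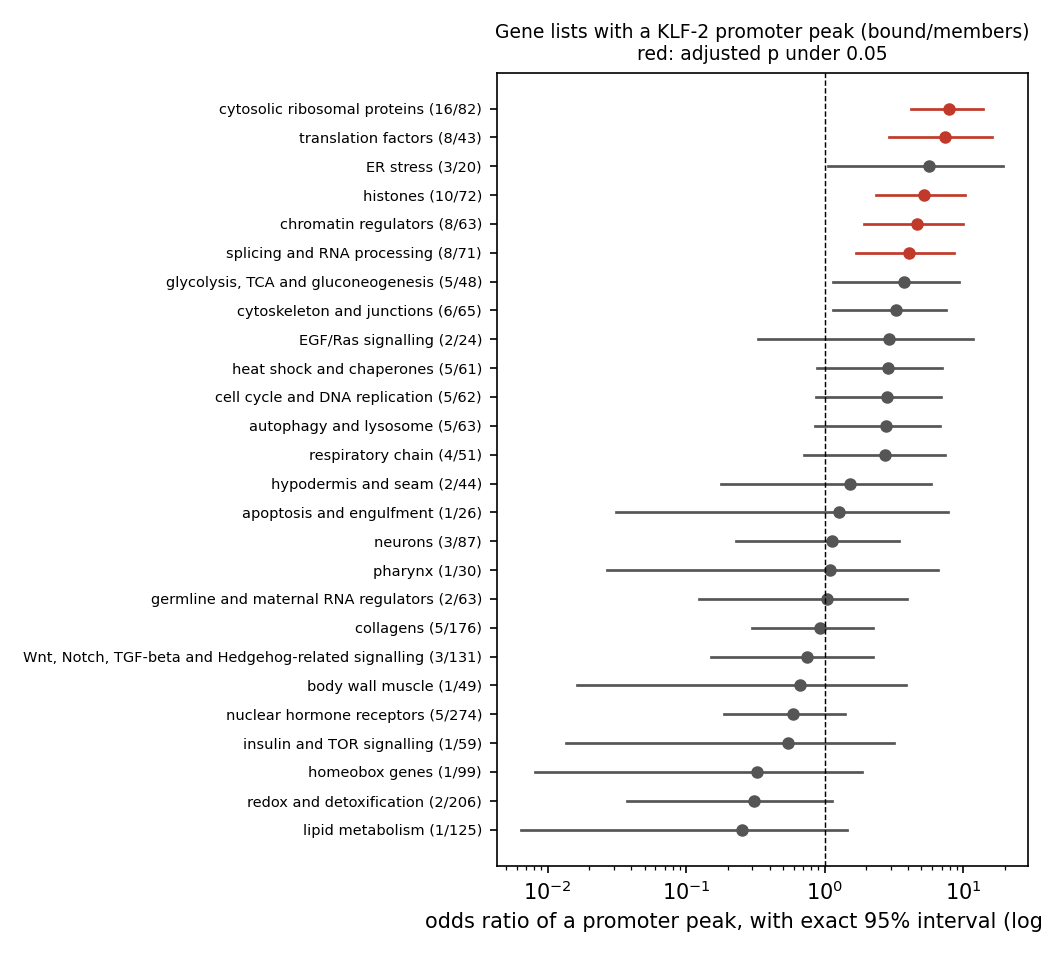
Odds ratio of a promoter peak for each gene list with at least 1 bound member (points), with exact 95% intervals (lines) on a log axis; red marks an adjusted p under 0.05 and the dashed line is an odds ratio of 1. Ribosomal protein genes are highest at 7.88, and lipid metabolism lowest at 0.255.

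The KLF/SP family itself had no peak of the conservative list in the promoter window of any of its 6 genes. The promoter of klf-2 held a peak of the ranked list on chromosome V from 20685473 to 20685768, with its summit 62 bp upstream of a transcript start and a signal value of 64.2, but its global IDR of 0.0522 was above the 0.01 of the thresholded list. The strongest ranked peak of sptf-3 had a signal value of 44.8 with its summit 41 bp upstream (global IDR 0.140). Values were lower at klf-3 (31.6, global IDR 0.424), sptf-1 (26.3, 0.779) and klf-1 (22.5, 0.501), and sptf-2 had no ranked peak in its promoter window.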

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

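Peaks outside the conservative list drew attention because they are among the strongest signals in the deposited files. In the ranked list of both replicates 1208 peaks reached a global IDR of 0.01 or better, and 176 of them are absent from the conservative list. Their median signal value was 182, against 93.9 in the conservative list, and 20 of them exceeded its maximum of 873. The highest reached 5615.3, on chromosome X from 15810934 to 15811225, followed by 3393 on X from 11785706 to 11785951. Of the 176, 156 (88.6%) lay more than 300 bp from any annotated gene, against 17.7% of the conservative peaks, and 0 were within 100 bp of a tRNA gene. The notes deposited with the samples list 1 further input file for the thresholded lists that the ranked lists lack, and that file was not analysed here. No explanation was tested.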

How the results depend on the processing

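Of the alternatives, those leaving out peaks at small-RNA genes, keeping 1 peak per pair of component peaks, searching the centre as 1 stretch and all those for the tRNA and snoRNA shares were chosen after seeing the data. The overlap of the replicates (61.0 to 78.4%), their rank correlation (0.600 to 0.705), the promoter share (34.5 to 58.3% over all windows), the upstream share (74.2 to 87.4%), the tRNA share (15.4 to 30.4%), the snoRNA share (0.969 to 8.77%) and the CCRCCC share (11.8 to 19.6%) kept their direction and, where tested, their side of the threshold in every alternative run. The alternatives are not independent, since they largely reuse the same peaks. The main and the other series-level list had 831 matches with identical coordinates. The count of fixed motifs ran from 10 to 15, with 10 motifs called in every alternative, while AGGTCA lost its call in 5 of 7 and the PHA-4 sequence in 3, and E-box CAGCTG, E2F, heat shock and Sp1-like sequences gained one in 1 or 2. The X share changed direction relative to its expected value without peaks at small-RNA genes (12.2%) and against X's share of bases (17.5%). The share on autosome arms lost its call with the 516 peaks of best IDR (65.1%), with the 516 of highest signal value (65.5%), against the share of bases (69.7%) and in each replicate alone (62.9 to 63.6%). The cause was not tested. Each replicate alone gave 436 to 456 peaks, 506 to 554 6-mers and 3 to 4 gene lists, from fewer peaks. Without peaks at small-RNA genes 465 6-mers passed, fewer than in smaller lists of peaks, and that setting also takes out the sequences of those genes. The number of gene lists was 2 with the 516 peaks of best IDR, 2 with the 516 of highest signal value, 2 with the nearest gene only and 10 with the promoter window from 2000 bp upstream, against 5. Among single lists, 16 calls were lost and 9 gained over all alternatives. No paired analysis was possible because there was 1 group. Read depth is unknown, so peaks missed for lack of reads cannot be counted.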

Other observations

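Some tests below were chosen only after the result was seen: CCRCCC without peaks at small-RNA genes, the comparison of KLF boxes with other 6-mers, the p of the shuffles and the test of tissue genes. Every small-RNA class was examined after the data were seen. The test of identical tRNA copies and the comparison of GGTTC were added after the result for unshared tRNA genes was known, and before their own values were. The design holds no second group, so no biological explanation that rests on a comparison of groups was tested for any pattern.

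Beyond tRNA and snoRNA genes, peaks marked 5 microRNA genes, with signal values of 322 at mir-51 and 221 at mir-52 on chromosome IV (0.484% of peaks against 0.0768% at random, permutation p = 0.008, adjusted p = 0.010). Genes of the SL2 spliced leader, sls-2.4 (174) and sls-2.1 (97.6), were among the 7 snRNA genes. Of the 53 peaks at snoRNA genes, 31 lay inside a protein-coding gene. The marked tRNA genes were spread over chromosomes and amino acids: 32.2% of the 276 tRNA genes on X had a peak, against 28.2 to 40.9% on the autosomes. Whether tRNA genes of some amino acids carry peaks more often was tested over 20 isotypes of 12 to 55 genes. Shares ran from 16.7% to 53.8%, and the smallest adjusted p was 0.878 (Fisher's exact tests). With so few genes per isotype, this does not show that the isotypes are alike, and the reading fixed beforehand, that no isotype past the threshold would argue against a difference, was withdrawn after the result was seen.

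For the 198 peaks at tRNA genes, base composition is argued against as the whole cause. Random sites matched to the summits on GC content of the central 100 bp lay at tRNA genes in 0.514% of cases on average. Over 1000 placements the highest share was 1.65%, against 19.2% observed. KLF boxes within 150 bp were not detectably more frequent at tRNA genes with a peak (odds ratio 0.957, 95% interval 0.615 to 1.47). This cannot decide on boxes inside the genes, because identical copies occur with and without a peak. At the 198 peaks CCRCCC was in 22 centres against 7 flanks (exact McNemar p = 0.00813), a surplus not set against base composition. Reads of near-identical copies remain a candidate source: none of the 25 tRNA genes that share no 36-base stretch with another place had a peak (0%, up to 13.7%), against 34.8% of the other 587 (Fisher's exact p = 4.1e-05), and the internal promoter sequence GGTTC was in 88.0% of the former and 89.3% of the latter. For reads spread evenly over identical copies, 93.6% of 47 sets of identical copies with a peak also held a copy without one. By the reading fixed beforehand this goes against even spreading. It cannot exclude it, because only peaks of the thresholded list were counted and weaker signal at the other copies was not examined. General recovery of strongly transcribed genes in the immunoprecipitation stays open and untested: the odds ratio of ribosomal protein genes without small-RNA peaks, planned as its test, decides nothing, because leaving out those peaks took away 0 of the 16 bound genes. The treatment of reads mapping to several places is unknown, and no untagged sample was analysed here to set such recovery apart from binding by KLF-2.

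The KLF boxes at the summits may follow in large part from base composition. Centres shuffled with their dinucleotides kept held CCRCCC in 10.1% of peaks on average and in up to 12.6% over 200 shuffles, a range fixed beforehand as the test, which takes in the observed 12.1%, although only 5 shuffles reached it (one-sided permutation p = 0.0299). Among 6-mers with as many G or C, CCACCC and CCGCCC had a mean percentile of 46.8 by the ratio of centre to flank. Peaks at small-RNA genes are not the source, since the surplus remained without them (exact McNemar p = 6.68e-10). What stays open is whether a small surplus exists beyond composition, and whether GC-rich sequence is itself the preferred substrate of the tagged protein or of the assay.

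The enrichment of ribosomal protein genes was set against 2 technical explanations. Small-RNA genes inside or beside them are argued against, because none of the 16 bound genes was lost without peaks at such genes. The odds ratio was then 9.18, with a lower bound of 4.92. It adds no further evidence, since with the same 16 genes bound it could not fall. Promoter GC content, with a median of 38.6% in ribosomal protein genes and 35.3% in all genes, is argued against as the whole cause, because the common odds ratio over 10 strata of GC content was 4.70 (95% interval 2.69 to 8.20), lower than the 7.88 without strata. Strong transcription of these genes stays open and could not be tested, since no expression values were analysed here.

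A further hypothesis was that the excess of peaks on chromosome X comes from the tRNA genes there. Peaks at small-RNA genes were on X in 87 of 259 cases (33.6%), and the remaining peaks in 12.2%, below the 14% of transcript starts, which is consistent with that reading. It was also asked whether genes of differentiated tissues and lineage regulators carry fewer peaks than others. Over 7 lists together 7 of 299 genes were bound (2.34% against 3.06%; odds ratio 0.758, 0.301 to 1.59, Fisher's exact p = 0.610), and the interval leaves both fewer and more peaks possible.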
